A study of Mus musculus with 3 samples.

How the data were processed

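The deposited tables hold counts of transcripts per gene and barcode, and were taken here as UMI counts of the 10x 3' v3 assay. Per the submitters' processing notes, reads were aligned to mm10 with STAR 2.5.3a. The counting program, the treatment of intronic reads and the annotation are not given in the sources used here. Per the labels' protocols, cells came from fresh lung digested with collagenase and DNAse and passed over a density gradient, and nuclei came from snap-frozen lung lysed in a nucleus isolation buffer. The cells and the nuclei were deposited in separate tables, and the nucleus libraries were told apart by the names of the columns, per the file headers. Barcodes had been filtered before deposit, with largest gene counts of 2499, 2499 and 2999 in cells, nucleus replicate 1 and nucleus replicate 2.

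The tables shared 21507 genes, and 1081 genes held by the cell table only and 1133 held by the nucleus table only were left out of comparisons (0.0392% and 0.0228% of counts). Barcodes with at least 400 genes and under 20% mitochondrial UMIs were kept. Doublets were scored per library by an own implementation of the Scrublet method, with its automatic threshold. It marked 5, 25 and 146 barcodes, and removed only the 146 of nucleus replicate 2, since calls under 0.5% of a library were kept by rule. This left 11934 cells and 6841 and 9660 nuclei. Each table was clustered alone by the Leiden method at resolution 1, with 2000 variable genes, 30 principal components and 20 neighbours. Clusters were named from fixed markers, where at least 3 markers of a class were 2-fold higher in the cluster and present in 10% of its barcodes, and where its 10 leading genes held no more markers of another class. A cluster with markers of an unrelated lineage scoring at least 0.5 of its own was called mixed and left out of every class. This rule was chosen after seeing the data. The mixed clusters held 350 cells and 23 nuclei, and 25 and 15 nuclei stayed unnamed. Shares carry exact binomial 95% intervals.

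For detection and for free RNA each barcode was thinned at random to 1000 UMIs, which left out 253 barcodes of nucleus replicate 2. The ratio of detected genes, cells over nuclei, was 1.04, against 1.03 at 500 UMIs and 1.05 at 2000 UMIs. Counts were summed per library, over all barcodes or per class, and tested with edgeR's quasi-likelihood method after TMM scaling and filterByExpr. Every p in the report is from edgeR, adjusted by the Benjamini-Hochberg method within a comparison, and CPM values are TMM-scaled except those for free RNA. The fit used 2 nucleus libraries and 1 cell library. The 16 classes with at least 50 barcodes in every library were compared, and monocytes (33 in nucleus replicate 1) were not. Named genes had at least 50 CPM in 1 group, a change of at least 2-fold, an edgeR adjusted p under 0.05 and both nucleus libraries on the same side of the cells. They were the leading 12 per direction over whole libraries and 6 per class. Members of the fixed lists and markers are named in addition, and ribosomal protein, mitochondrial and clone-like symbols were treated as groups. Results for some genes that met these rules are not reported here. Where a group had 0 counts the fold is a bound against 3 counts, and at 1 to 3 counts a ratio with a counting interval is given.

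In a self-test with 50 genes set to change by each of 2, 4, 8 and 16-fold, edgeR recovered 4, 30, 96 and 98% of them over whole libraries, with 1 false call among 115. In AT2 it recovered 6, 52, 100 and 98%, with 7 false calls among 135. Small changes were mostly missed in this simulation. It gave all genes 1 common dispersion, let the cell library vary like the nuclei and changed 200 genes in all. The data gave far more calls, and the spread of the cell library is not known. The recovery and false calls of the simulation therefore need not hold for the data.

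The 14 gene lists were fixed before the data were examined: immediate early genes, heat shock genes, inflammatory cytokines and chemokines, mitochondrial transcripts, cytosolic ribosomal proteins, nuclear genes of oxidative phosphorylation, nuclear long non-coding RNAs, haemoglobin, extracellular matrix and basement membrane, vascular growth factors and receptors, surfactant, viral entry factors, apoptosis and p53 targets, and cell cycle. The list and marker genes Krt17, mt-Nd4, mt-Co3, Snhg14, Gas5, Mir99ahg and Norad were not analysed here, and Cyr61 was analysed under its current symbol Ccn1. The median log2 fold of each list was ranked among 10000 random lists drawn from the 100 genes nearest in expression to each member. In a self-test with simulated folds and lists of 20 genes, 7 of 100 unshifted lists fell outside the central 95%, and 98 of 100 lists shifted by a log2 fold of 2 did. The simulated folds were independent of each other, whereas members of a real list can vary together. These rates therefore need not hold for the real lists. Gene positions and lengths are those of GENCODE M21, and 99.2% of the tested genes had a length.

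The settings tried besides were DESeq2 in place of edgeR, DESeq2 size factors, library sizes without mitochondrial and ribosomal protein genes and Malat1, no filter on low counts, doublets kept or the highest 5% of scores removed, other limits of genes and mitochondrial share, other resolutions and a larger set of variable genes, and each nucleus library left out. Settings added after seeing the data were a common window of 1300 to 2499 genes, mixed clusters named from their best class, lists matched on gene length, and wider use of kept doublets and of leaving out a library. Versions were R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, limma 3.58.1, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, scikit-image 0.26.0 and matplotlib 3.10.9.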

Results

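Lung of wild type C57Bl/6J mice was profiled by droplet RNA sequencing in 3 libraries, 1 of dissociated cells and 2 of isolated nuclei, to compare the 2 ways of preparing the tissue. The cells were released from fresh lung by enzymatic digestion, and the nuclei were taken from snap-frozen lung lysed in a detergent buffer. Preparation and fresh or frozen tissue therefore differed together between the groups, and whether the animals differed too is not given in the labels. The labels name no separate animals, so the p-values below measure only the spread between these samples, which may be technical in part. Xist stood at 1041 and 8.80 CPM and Uty at 0.943 and 245 CPM in nucleus replicates 1 and 2, so these were not both made from 1 and the same animal. The cells, like nucleus replicate 1, had far more Xist than Uty. They were therefore not made from the same single animal as nucleus replicate 2 either. Values for nuclei are means ± SD of the 2 libraries (n = 2), and the cell library had no replicate.

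The cell library held 11934 barcodes and 35962788 counts, with a median of 2864 UMIs (quartiles 2346.25 and 3557.75) and 1719 genes per barcode. Nucleus replicate 1 held 6849 barcodes and 28062109 counts with medians of 4152 UMIs and 2006 genes. Nucleus replicate 2 held 9806 barcodes and 27148272 counts with medians of 2521 UMIs and 1540 genes. Transcripts of the mitochondrial genome took a median of 2.01% of the UMIs of a cell, against 0.301% and 0.240% of those of a nucleus. Ribosomal protein transcripts took 7.67% in cells and 0.847% in both nucleus libraries. Malat1, a long non-coding RNA held in the nucleus, took 1.01% in cells and 2.44% and 2.41% in nuclei. After each barcode was thinned to 1000 UMIs, the median number of genes was 764 in cells, 720 in nucleus replicate 1 and 754 in nucleus replicate 2. With no second cell library these differences were not tested. The order differed between classes. Alveolar macrophages had 747 genes in cells against 761 and 784 in nuclei, and dendritic cells 734 against 744.5 and 778. In AT2, B cells, T/NK/ILC2 and interstitial macrophages the cells lay between the nucleus libraries.

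Immune cells made up 53.9% of the cell library (exact 95% interval 52.96 to 54.75%) and 16.3% ± 2.39 of the nucleus libraries. Alveolar macrophages, the resident phagocytes of the airspace, took 19.0% of cells (18.3 to 19.7%) against 2.29% and 4.54% of nuclei. Monocytes took 11.3% (10.8 to 11.9%) against 0.482% and 2.14%, and dendritic cells 5.73% (5.32 to 6.16%) against 1.32% and 1.31%. Interstitial macrophages ran the other way, at 1.44% of cells (1.24 to 1.67%) against 3.20% and 2.13% of nuclei. The nucleus cluster given this name was, however, led by F13a1, a monocyte marker that also led a monocyte cluster of cells. The shares of interstitial macrophages and of monocytes may therefore compare unlike clusters. Epithelial barcodes were fewer among cells, at 6.55% of cells (6.12 to 7.01%) and 35.9% ± 11.4 of nuclei. Type 2 pneumocytes (AT2), which make surfactant, were 4.08% of cells (3.73 to 4.45%) against 19.7% and 16.7% of nuclei. Type 1 pneumocytes (AT1), which form the gas exchange surface, were 1.45% (1.24 to 1.68%) against 4.96% and 10.1%. Endothelial cells, at 23.0% of cells (22.2 to 23.8%), lay between the nucleus libraries, which had 37.7% and 19.9%. Mesenchymal cells were 13.7% of cells (13.1 to 14.3%) and 18.7% ± 1.15 of nuclei.

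Some classes were named in only 1 of the 2 groups. No cluster of cells was named club, the secretory cell of the airway, against 2.03% and 10.3% of nuclei, although the ciliated cluster of cells had club markers as its second set. Arterial endothelium was likewise named only among nuclei, at 2.18% and 2.89%, although the general capillary cluster of cells had arterial markers as its second set. Neutrophils, at 1.40% (1.20 to 1.63%), and basophils or mast cells, at 0.251% (0.170 to 0.359%), were named only among cells. Clusters with markers of 2 unrelated lineages were set apart as mixed, by a rule chosen after seeing the data. They held 350 cells, 2.93% of that library, with neutrophil and alveolar fibroblast or B cell and monocyte markers, and 2 and 21 nuclei. Shares carry no test between the groups, and the intervals cover counting error only. Barcodes in the deposited tables stop below 2500 genes in cells and nucleus replicate 1 and below 3000 in nucleus replicate 2. Barcodes above these limits are not in the tables used here, and their number per class is not known.

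**Figure D1:**
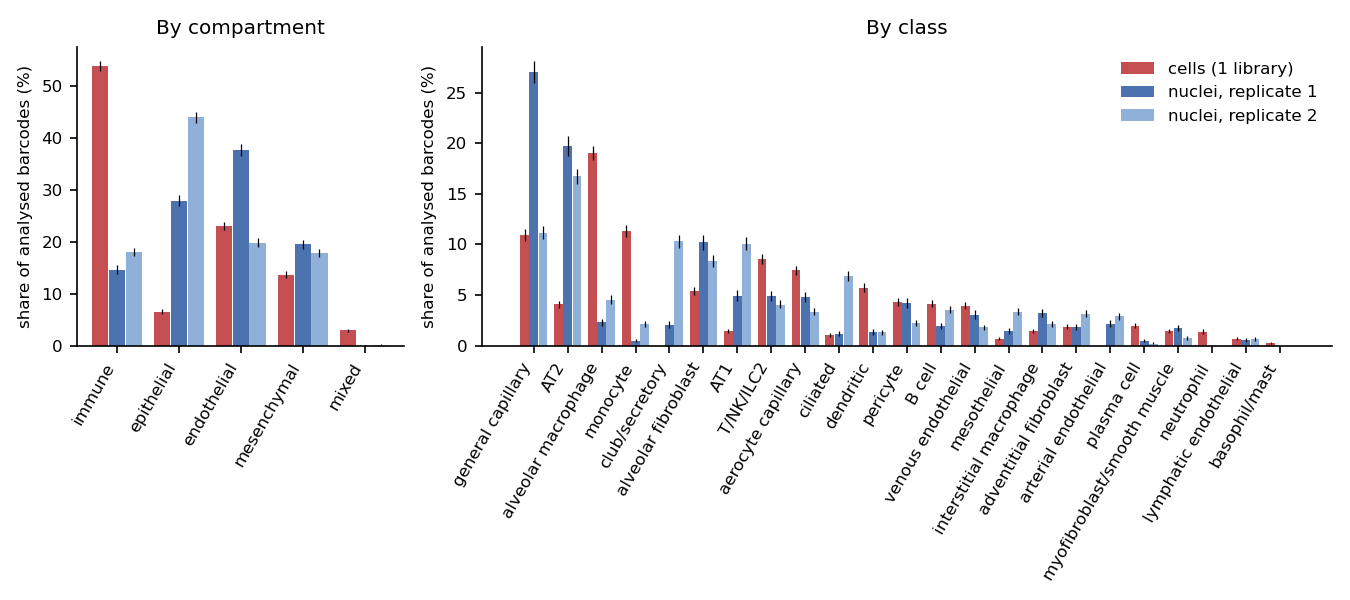
Percent of analysed barcodes (vertical axes) in each compartment and cell class (horizontal axes) for the cell library and nucleus replicates 1 and 2; bars are shares and whiskers exact 95% binomial intervals. Immune barcodes reach 53.9% in cells against 14.6% and 18.0% in nuclei, and epithelial barcodes 6.55% against 27.9% and 43.9%.

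Immediate early genes, which cells switch on within minutes of a stimulus, were far higher in cells over the whole libraries. Fosb, a subunit of the AP-1 transcription factor, stood at 638 CPM in cells and 0.475 ± 0.0568 CPM in nuclei (log2 fold 10.38, SE 0.44, adjusted p = 0.00418). Fos, of the same family, stood at 791 against 3.61 ± 0.287 CPM (log2 fold 7.78, SE 0.40, adjusted p = 0.00418), and Junb at 1825 against 16.2 ± 3.82 CPM (log2 fold 6.81, SE 0.47, adjusted p = 0.00418). The growth-response factor Egr1 stood at 972 against 5.00 ± 2.21 CPM (log2 fold 7.60, SE 0.54, adjusted p = 0.00419). Nr4a3, Atf3 and Dusp1 were higher by log2 folds of 6.74, 6.68 and 4.72 (adjusted p of 0.00418, 0.00418 and 0.00588). Of the 35 immediate early genes tested, 33 were higher in cells and 0 lower, and the counts adjusted over the list alone were also 33 and 0. The exceptions were Fosl1 (log2 fold -0.11, adjusted p = 0.918) and Tsc22d3 (0.84, adjusted p = 0.431). Fosb lies on chromosome 7 (19302696 to 19310051 of mm10), Fos on chromosome 12 (85473890 to 85477273), Junb on chromosome 8 (84974484 to 84978718) and Egr1 on chromosome 18 (34859823 to 34864984).

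Inflammatory cytokines and chemokines were higher in cells in 12 of 14 members tested and lower in 0, with 13 and 0 adjusted over the list alone. The neutrophil attractant Cxcl2 (chromosome 5, 90903871 to 90905938) stood at 189 against 0.196 ± 0.0823 CPM (log2 fold 9.89, SE 0.45, adjusted p = 0.00418), and Cxcl1 at 11.3 against 0.178 ± 0.0567 CPM (log2 fold 5.97, SE 0.59, adjusted p = 0.00625). Il1b stood at 197 against 2.55 ± 1.30 CPM (log2 fold 6.27, adjusted p = 0.00539; 5.83 and 6.91 without nucleus replicate 1 or 2). The adhesion molecules Icam1 (log2 fold 1.18, adjusted p = 0.0520) and Sele (0.63, adjusted p = 0.615) did not pass. Among myeloid genes, Wfdc17 stood at 105 against 1.16 ± 0.105 CPM (log2 fold 6.49, adjusted p = 0.00418). Trem3, Ccl4 and Ifitm6 were higher by log2 folds of 7.38, 7.25 and 6.64 (adjusted p of 0.00625, 0.00608 and 0.00625). Their folds rest on few nuclear counts, and became 6.68, 6.61 and 6.03 without nucleus replicate 1 and 8.82, 8.50 and 7.77 without nucleus replicate 2. Iqcn was higher by 6.49 (adjusted p = 0.00418). Iqcn begins 2841 bp downstream of Jund, and Trem3 begins 853 bp downstream of Trem1, each pair on 1 strand.

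Transcripts of the translation and respiration machinery were also higher in cells. Of 83 cytosolic ribosomal protein genes 81 were higher and 0 lower (82 and 0 adjusted over the list alone). Rps9 stood at 1971 against 132 ± 9.12 CPM (log2 fold 3.90, adjusted p = 0.00627), while Rps6 (log2 fold 1.56, adjusted p = 0.0929) and Rpl22l1 (0.88, adjusted p = 0.441) did not pass. All 11 transcripts of the mitochondrial genome tested were higher and 0 lower, the same counts as adjusted over the list alone. One of them, mt-Cytb, stood at 3638 against 206 ± 39.3 CPM (log2 fold 4.14, adjusted p = 0.00630). Of 85 nuclear genes of oxidative phosphorylation 62 were higher and 1 lower (64 and 3 adjusted over the list alone). Cox7a2l stood at 260 against 27.9 ± 2.38 CPM (log2 fold 3.22, adjusted p = 0.00625). The lower gene was Uqcrc2, a core subunit of complex III, at 11.2 against 28.9 ± 1.70 CPM (log2 fold -1.37, adjusted p = 0.0368). Among nuclear long non-coding RNAs 0 of 9 were higher and 1 lower (0 and 3 adjusted over the list alone). The lower one was Snhg11, at 4.87 against 103 ± 19.8 CPM (log2 fold -4.40, adjusted p = 0.00625). Malat1 had a log2 fold of -1.36 (adjusted p = 0.299) and Neat1, the scaffold of paraspeckles, -0.07 (adjusted p = 0.927).

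Most of the stress, death and division genes tested were higher in cells too. Of 16 heat shock genes 12 were higher and 0 lower (13 and 0 adjusted over the list alone), among them the chaperones Hsp90ab1 (999 against 139 ± 20.8 CPM, log2 fold 2.85, adjusted p = 0.00798) and Dnajb1 (log2 fold 3.90, adjusted p = 0.00625). Of 10 apoptosis and p53 target genes 6 were higher and 0 lower, the same counts as adjusted over the list alone. The cell cycle inhibitor Cdkn1a stood at 313 against 17.2 ± 2.47 CPM (log2 fold 4.19, adjusted p = 0.00537), and Pmaip1, which promotes apoptosis, had a log2 fold of 5.00 (adjusted p = 0.00439). Of 14 cell cycle genes 8 were higher and 0 lower (11 and 0 adjusted over the list alone). Ube2c, which marks proteins for destruction in mitosis, stood at 9.05 against 0.954 ± 0.0363 CPM (log2 fold 3.24, adjusted p = 0.0113). Haemoglobin transcripts, which mark red blood cells, were higher in 2 of 4 and lower in 0 (3 and 0 adjusted over the list alone). Hba-a2 had a log2 fold of 2.81 (adjusted p = 0.0136; 3.44 and 2.37 without nucleus replicate 1 or 2).

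Each list was also set against 10000 random lists matched on expression, by its median log2 fold. The medians of immediate early genes (3.48), cytokines (5.43), ribosomal proteins (3.36), oxidative phosphorylation (1.90) and cell cycle (2.24) lay at percentile 100, and that of heat shock genes (2.06) at percentile 99.98. Apoptosis and p53 targets (1.35) lay at 99.0 and haemoglobin (2.47) at 99.5. The haemoglobin median became 3.59 without nucleus replicate 1 and 1.80 without nucleus replicate 2. Mitochondrial transcripts (3.03) lay at 96.2 and long non-coding RNAs (-1.11) at 0.750. Without nucleus replicate 1 the mitochondrial median was 3.37, at percentile 99.1. Matched on gene length as well, a setting chosen after seeing the data, heat shock genes lay at 86.4, apoptosis at 64.0 and haemoglobin at 34.4, within the range of random lists. The apoptosis and p53 targets were also within it when only genes at 10 CPM or more in both groups were used.

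**Figure D2:**
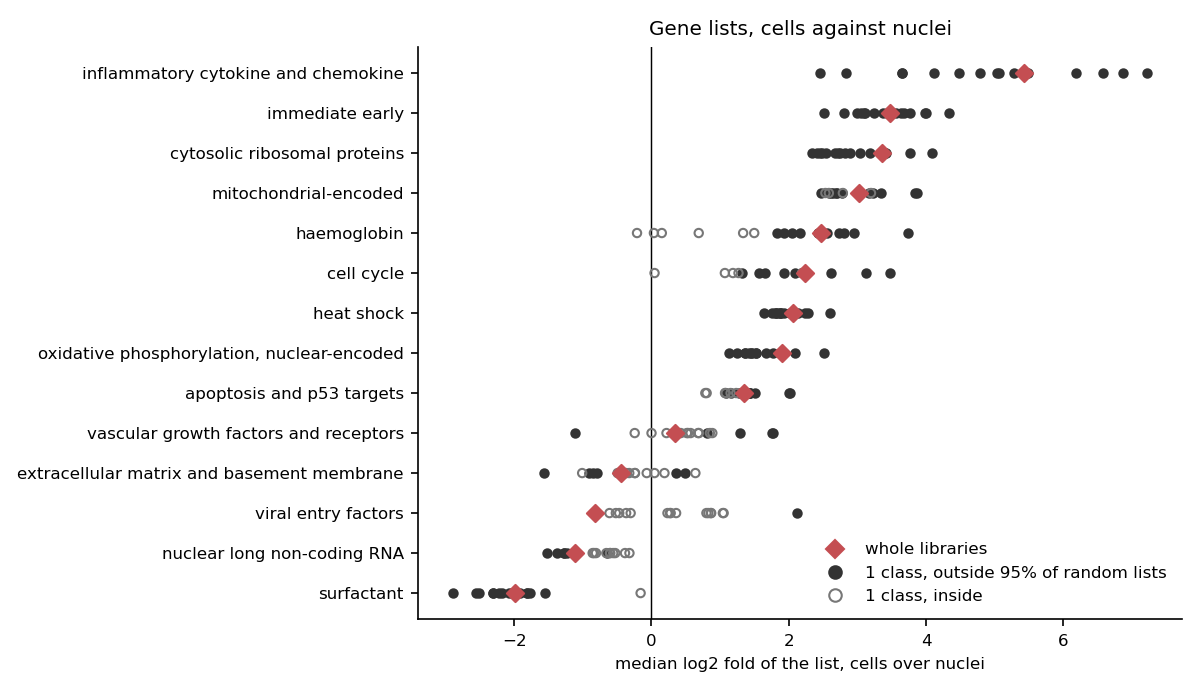
Median log2 fold of each gene list, cells over nuclei (horizontal axis, log2 scale), for the 14 lists (vertical axis); diamonds are whole libraries, and dots are the 16 cell classes, filled where the median lies outside the central 95% of 10000 matched random lists. Cytokine medians of classes are drawn from fitted folds, without bounds. Immediate early genes lie at 3.48 and surfactant genes at -1.98 over whole libraries.

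Genes of club cells were among those lower in cells over the whole libraries. Cyp2f2, a cytochrome P450 of club cells (chromosome 7, 27119909 to 27133660), stood at 22.6 CPM in cells and 617 ± 284 CPM in nuclei (log2 fold -4.77, SE 0.66, adjusted p = 0.00882). Scgb1a1, their main secreted protein, stood at 1532 against 15041 ± 775 CPM (log2 fold -3.30, SE 0.82, adjusted p = 0.0375). The aldehyde oxidase Aox3 reached 314 ± 13.2 CPM in nuclei (log2 fold -4.59, SE 0.44, adjusted p = 0.00625). The proton pump subunit Atp6v1c2, the magnesium channel Trpm6 and the meiotic gene Tex11 had log2 folds of -4.31, -4.20 and -4.83 (adjusted p of 0.00625, 0.00730 and 0.00629). Itprid1 (chromosome 6, 55836895 to 55978735) had a log2 fold of -6.62 (adjusted p = 0.0147), and the BMP receptor Bmpr1b (chromosome 3, 141837136 to 142169425) one of -5.28 (adjusted p = 0.0170). These 2 folds became -7.31 and -5.93 without nucleus replicate 1 and -5.22 and -4.07 without nucleus replicate 2. Ppp2r2b, Btg4 and Elfn1 were lower as well, by log2 folds of -4.84, -4.42 and -4.28 (adjusted p of 0.0279, 0.0339 and 0.0125). Their folds became -5.55, -5.14 and -3.50 without nucleus replicate 1 and -3.36, -2.94 and -4.79 without nucleus replicate 2.

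Of 10 surfactant genes 0 were higher and 7 lower in cells, with the same counts adjusted over the list alone and a list median of -1.98 at percentile 0 of the matched lists. Etv5, a transcription factor of AT2 cells, stood at 37.6 against 413 ± 72.7 CPM (log2 fold -3.45, SE 0.45, adjusted p = 0.00793), and Sftpb at 167 against 792 ± 111 CPM (log2 fold -2.24, SE 0.45, adjusted p = 0.0219). Sftpc, the AT2 surfactant protein with the most counts, stood at 3177 against 2919 ± 98.2 CPM (log2 fold 0.12, SE 0.52, adjusted p = 0.878). Of 26 extracellular matrix and basement membrane genes 3 were higher and 3 lower (4 and 5 adjusted over the list alone), with a median of -0.45 at percentile 4.73. The fibrillar collagen Col1a1 (log2 fold 1.75, adjusted p = 0.0326), Fn1 (1.85, adjusted p = 0.0254) and Fbln1 (1.31, adjusted p = 0.0435) were higher. The basement membrane genes Col4a3 (-3.05, adjusted p = 0.0154), Col4a4 (-3.14, adjusted p = 0.0168) and Lama4 (-1.24, adjusted p = 0.0494) were lower. Without nucleus replicate 1 the matrix median was -0.49, at percentile 1.03.

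Of 20 vascular growth factors and receptors 3 were higher and 1 lower (2 and 0 adjusted over the list alone), with a median of 0.34 at percentile 81.1. Apln, a peptide of aerocyte capillaries, stood at 31.9 against 2.18 ± 0.616 CPM (log2 fold 3.87, SE 0.41, adjusted p = 0.00627). The VEGF receptor Kdr (1.81, adjusted p = 0.0234) and Angptl2 (1.69, adjusted p = 0.0427) were higher, and Vegfd (-1.17, adjusted p = 0.0473) lower. With genes at 10 CPM or more in both groups only, the vascular median turned to -0.40, at percentile 19.3. Of 10 viral entry factors 3 were higher and 3 lower (4 and 5 adjusted over the list alone), with a median of -0.83 inside the central 95% of the matched lists. The lysosomal proteases Ctsb (2.78, adjusted p = 0.00981) and Ctsl (2.11, adjusted p = 0.00830) and the protease Furin (1.77, adjusted p = 0.0128) were higher. Among the lower genes were the proteases Tmprss4 (-3.03, adjusted p = 0.0206) and Anpep (-2.20, adjusted p = 0.0157). The viral entry median turned to 1.33, at percentile 97.0, with genes at 10 CPM or more in both groups. It was -0.95, at percentile 1.47 and below that range, without nucleus replicate 2, and lay below it at percentile 1.01 when lists were matched on length too.

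Over whole libraries 19790 genes were tested with edgeR, of which 3146 were higher and 1535 lower in cells at an adjusted p under 0.05. The fit had 1 residual degree of freedom, and the cell library was assumed to vary like the nucleus libraries. DESeq2 called 2945 higher and 2222 lower, and 4402 of its 5167 calls were shared with edgeR, all in the same direction. Whole-library values mix changes within cell types with the different shares of those types.

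Within cell classes the same immediate early genes stood out. Fosb, Fos, Egr1, Junb and Atf3 were higher in cells in 16 of 16 classes. So were the cytoskeletal gene Actb and Iqcn, which is not on the immediate early list and lies downstream of Jund. Of 5939 genes tested in every class, 304 were higher in cells in all 16, among them 74 of 78 ribosomal protein genes, 11 of 11 mitochondrial transcripts and 20 of 28 immediate early genes. Only 7 genes were lower in all 16: Ccdc141, Dgcr8, Etv5, Kctd8, Scgb1a1, Scgb3a2 and Tmem212. The club gene Cyp2f2 was lower in 15 of 16 classes. In the other direction 564 genes were higher in some classes and lower in others, such as Sftpc, which was higher in AT2 cells and lower in 14 other classes. Under DESeq2 the calls ended for Iqcn in pericytes, Egr1 in AT1 and Kctd8 in mesothelium, and without the filter on low counts for Kctd8 in dendritic cells. Each class rested on different clusters in the 2 groups, since the tables were clustered apart. In 6 classes (B cells, T/NK/ILC2, aerocytes, alveolar macrophages, myofibroblast or smooth muscle and venous endothelium) edgeR took each gene's spread from the trend over all genes, which gives very small p-values.

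Per class, 3075 genes were higher and 2334 lower in AT2 cells, and 3173 and 2049 in alveolar macrophages. AT1 cells gave 1626 and 696, ciliated cells 1254 and 976, B cells 1119 and 708, T/NK/ILC2 cells 1846 and 1070, and dendritic cells 855 and 127. Interstitial macrophages gave 1196 and 394, aerocytes 2123 and 1260, general capillaries 1875 and 851, and venous endothelium 1511 and 553. Alveolar fibroblasts gave 1979 and 919, adventitial fibroblasts 1575 and 942, pericytes 1439 and 782, myofibroblast or smooth muscle 1240 and 644, and mesothelium 1100 and 558. The split between higher and lower depended on the scaling. With library sizes that leave out mitochondrial and ribosomal protein genes and Malat1, it was 1768 and 267 in AT1, 972 and 845 in B cells, 2224 and 2827 in alveolar macrophages, 1339 and 573 in ciliated cells and 1252 and 1072 in dendritic cells. It was 1217 and 827 in interstitial macrophages, 1999 and 759 in aerocytes and 2035 and 539 in alveolar fibroblasts under that scaling. It also gave 2521 and 1431 in AT2, 971 and 688 in T/NK/ILC2, 1504 and 450 in general capillaries and 841 and 292 in myofibroblast or smooth muscle.

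That scaling moved the median log2 fold of all genes by over 0.1 in 11 classes, to 0.17 in AT1, 0.12 in AT2, -0.14 in B cells, -0.19 in T/NK/ILC2 and 0.18 in aerocytes. The other medians became 0.16 in alveolar fibroblasts, -0.34 in alveolar macrophages, 0.13 in ciliated cells, -0.31 in dendritic cells, -0.20 in interstitial macrophages and 0.19 in pericytes. The main medians lay between -0.08 and 0.02. DESeq2 size factors gave 1638 and 875 in interstitial macrophages and 996 and 222 in dendritic cells. The DESeq2 test called fewer genes in total in every class, such as 1343 and 581 in alveolar macrophages, 565 and 259 in aerocytes, 340 and 196 in B cells and 1554 and 1146 in AT2. It gave 318 and 156 in ciliated cells, 586 and 229 in dendritic cells, 283 and 22 in mesothelium and 329 and 60 in venous endothelium. AT1 gave 1999 and 1841 without the filter on low counts, dendritic cells 202 and 2, interstitial macrophages 1576 and 762, and myofibroblast or smooth muscle 1148 and 427. With doublets kept, dendritic cells gave 1519 and 687, interstitial macrophages 1606 and 905, and venous endothelium 597 and 67. Alveolar fibroblasts then gave 1529 and 451, mesothelium 911 and 314, and pericytes 1815 and 1189.

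In AT2 cells the surfactant genes divided. Sftpc stood at 50247 CPM in cells and 5261 ± 966 CPM in nuclei (log2 fold 3.26, SE 0.69, adjusted p = 0.00300), and Sftpa1 at 4908 against 681 ± 14.4 CPM (log2 fold 2.85, SE 0.46, adjusted p = 0.000456). Without TMM scaling, Sftpc stood at 4275 and 6278 CPM in AT2 nuclei of replicates 1 and 2. In B cell nuclei it stood at 3810 and 5941 CPM, so its nuclear value and its fold in AT2 carry background. Etv5 stood at 387 against 1995 ± 91.0 CPM (log2 fold -2.37, SE 0.51, adjusted p = 0.00327), and the lipid transporter Abca3 was lower by a log2 fold of -1.55 (adjusted p = 0.0202). Sftpb had a log2 fold of -0.07 (adjusted p = 0.924) and Lamp3 of -1.18 (adjusted p = 0.0610). Fosb, Egr1 and Atf3 were higher by log2 folds of 9.81, 8.94 and 7.59 (adjusted p of 2.08e-07, 3.47e-07 and 2.45e-07). In AT1 cells the receptor gene Ager was higher by 3.47 (adjusted p = 0.00281; 2.95 and 4.32 without nucleus replicate 1 or 2), and the tight junction gene Cldn18 by 1.45 (adjusted p = 0.0305). Rtkn2 was lower by -1.66 (adjusted p = 0.0248), at 3515 against 11126 ± 3211 CPM. In ciliated cells the long genes of the axoneme Dnah12 (-1.69, adjusted p = 4.89e-06), Hydin (-1.41, adjusted p = 0.000127) and Spag17 (-1.10, adjusted p = 0.00295) were lower. Foxj1, the master regulator of motile cilia, was higher by 1.10 (adjusted p = 0.0170) and Dynlrb2 by 0.91 (adjusted p = 0.0274). Catsperd, with 3 counts in ciliated cells, had 3 counts in nucleus replicate 1 and 1666 in nucleus replicate 2, so its call rests on that library, and it ended under DESeq2. The Cyp2f2 that was lower in AT1 (log2 fold -4.77, adjusted p = 0.00144) and AT2 (-4.16, adjusted p = 6.30e-05) belongs to club cells.

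In general capillary cells Gpihbp1, which carries lipoprotein lipase, stood at 395 CPM in cells and 53.2 ± 9.14 CPM in nuclei (log2 fold 2.90, SE 0.38, adjusted p = 0.00112). Cd93 (2.41, adjusted p = 0.00338) and the shear-responsive factor Klf2 (2.37, adjusted p = 0.00242) were higher as well, whereas Ptprb did not pass (0.27, adjusted p = 0.716). Egr1 was higher by 8.57 (adjusted p = 1.53e-05). Aerocytes, the capillary cells facing the airspace, had Apln at 248 against 12.8 ± 5.60 CPM (log2 fold 4.33, SE 0.42, adjusted p = 2.36e-22). Kdr (1.59, adjusted p = 0.00326) and the endothelin receptor Ednrb (1.40, adjusted p = 0.00638) were higher there, and Car4 did not pass (0.51, adjusted p = 0.383). Fosb had 1021 counts in aerocytes and 0 in either nucleus library, at least 273-fold higher against a floor of 3 counts over the nuclei. In venous endothelium Vcam1 was higher by 1.45 (adjusted p = 0.00408) and Vwf did not pass (-0.25, adjusted p = 0.767). Muc13 had 315 counts in venous cells and 0 in nuclei, at least 102-fold higher.

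In alveolar fibroblasts the transcription factor Tcf21 stood at 167 CPM in cells and 37.0 ± 16.9 CPM in nuclei (log2 fold 2.16, SE 0.41, adjusted p = 0.00144), Inmt was higher by 1.80 (adjusted p = 0.00708) and Col1a2 by 2.12 (adjusted p = 0.00195). Egr1 and Fos were higher there by 8.48 and 8.32 (adjusted p of 9.10e-08 for both). In adventitial fibroblasts the proteoglycan gene Dcn stood at 5417 against 288 ± 16.4 CPM (log2 fold 4.23, SE 0.38, adjusted p = 3.89e-10), and Clec3b was higher by 3.49 (adjusted p = 1.52e-08). The glutamate receptor gene Gria1, at 12.2 against 327 ± 8.91 CPM, was lower by -4.72 (adjusted p = 4.06e-08). In pericytes Higd1b was higher by 3.65 (adjusted p = 0.000350), and the cation channel Trpc6, at 908 against 4013 ± 1320 CPM, was lower by -2.14 (adjusted p = 0.0298). Pdgfrb did not pass in pericytes (-0.54, adjusted p = 0.368). In mesothelium Msln was higher by 2.12 (adjusted p = 0.000190; 1.63 and 2.96 without nucleus replicate 1 or 2), and Gpm6a did not pass (-0.40, adjusted p = 0.465). The cluster of the muscle class was named myofibroblast among cells and smooth muscle among nuclei, each with the other's markers as its second set. Hhip, Kctd16 and Myh11 were among the leading genes of both clusters. The genes of this class are not described further.

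In alveolar macrophages the ribonuclease genes Ear1 and Ear2 stood at 915 and 1670 CPM in cells and at 17.3 ± 4.96 and 63.0 ± 6.51 CPM in nuclei (log2 folds 5.65 and 4.74, adjusted p of 5.80e-54 and 2.50e-44). Marco, a scavenger receptor, was higher by 3.35 (adjusted p = 1.04e-22) and Fabp1 by 5.33 (adjusted p = 3.91e-44), whereas the mannose receptor Mrc1 did not pass (0.18, adjusted p = 0.664). Cxcl2 had 3524 counts in alveolar macrophages and 1 in nuclei, a ratio of 1233 with a counting interval of 221 to 48700. In interstitial macrophages Apoe stood at 3142 against 115 ± 24.4 CPM (log2 fold 4.78, SE 0.37, adjusted p = 0.000197). C1qb, a complement component, was higher by 4.55 (adjusted p = 0.000260) and Il1b by 6.22 (adjusted p = 0.000132). In B cells the antigen receptor chain Cd79a (2.79, adjusted p = 6.17e-09) and the surface protein Ms4a1 (3.44, adjusted p = 5.58e-12) were higher. The transcription factor Pax5 (-0.77, adjusted p = 0.308) and Bank1 (-0.79, adjusted p = 0.337) did not pass. In T/NK/ILC2 the T cell receptor chain Cd3d was higher by 4.62 (adjusted p = 4.62e-20), and Themis did not pass (0.13, adjusted p = 0.862). This class, the dendritic class and the interstitial macrophage class differed in make-up. The interstitial macrophage cluster was led by C1qa among cells. Among nuclei it was led by the monocyte marker F13a1 and had dendritic markers as its second set, so its calls may compare unlike cells. NK cells and ILC2 had clusters among cells only, and dendritic cells had 4 clusters among cells (marked by Cd209a, Xcr1, Siglech or Ccr7) and 1 among nuclei, marked by Itgae.

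Within classes the lists were matched on expression only, not on gene length. Over whole libraries, matching on length too had put the heat shock, apoptosis and haemoglobin lists within the range of random lists. The immediate early list had a positive median in every class, from 2.51 to 4.34, above the central 95% of its matched lists in 16 of 16. Heat shock genes (1.64 upwards), ribosomal proteins (2.34 to 4.09) and oxidative phosphorylation (1.13 to 2.51) lay above it in 16 classes as well. Cytokines did so in 16 classes too, with medians from 2.46 to 5.67 when members at 0 to 3 counts in a group were set to their bound or ratio. Mitochondrial transcripts lay above it in 12 classes (2.46 to 3.87) and haemoglobin in 10 (-0.21 to 3.74). Apoptosis and p53 targets did so in 10 (0.78 to 2.02) and cell cycle genes in 9 of 14 (0.04 to 3.47). The surfactant list lay below its matched lists in 15 classes, with AT2 cells, their source, the exception at a median of -0.16. Long non-coding RNAs lay below it in 6 classes (-1.52 to -0.32). Matrix genes lay above in alveolar fibroblasts (0.49) and adventitial fibroblasts (0.36), and below in B cells (-1.56), T/NK/ILC2 (-0.91), alveolar macrophages (-0.85) and ciliated cells (-0.79). Their members Col4a3 and Col4a4, leading genes of an AT1 cluster of nuclei, were lower in cells in at least 12 classes. The lower matrix medians were therefore not told apart from RNA of AT1 nuclei counted in those classes. Vascular genes lay above in pericytes (1.77), AT2 (1.75), AT1 (1.30) and aerocytes (0.81), and below in B cells (-1.11). Viral entry factors lay above in mesothelium alone (2.12). Leukocyte genes such as Tyrobp, Laptm5, Cd28 and Gzma were also higher in cells in all 16 classes, those outside the immune compartment included. The rise of cytokines in such classes was therefore not told apart from RNA of immune cells counted there.

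Short genes were higher in cells and long genes higher in nuclei. The median log2 fold was 1.53 for the 230 genes under 1 kb, 0.83 for the 3845 genes of the bin that ends at 10 kb and -0.90 for the 542 genes of the longest bin. Genes under 10 kb had a median of 0.87 and genes of 100 kb or more one of -0.71, a difference of 1.58. The Spearman correlation of length and fold was -0.33 across genes, which are not independent replicates. Every class showed the same order, with differences from 1.63 in AT2 to 2.76 in dendritic cells. Without mitochondrial and ribosomal protein genes the difference over whole libraries was 1.54. Single genes did not all follow this order. Among genes higher in cells, Fos at 3384 bp and Cxcl2 at 2068 bp are short, but Atf3 spans 47744 bp and Nr4a3 41295 bp. Among genes lower in cells, Itprid1 and Bmpr1b are long, but Scgb1a1 spans only 4323 bp. Whether intronic reads were counted in either kind of library is not given in the sources used here, and counting them would itself raise long genes in nuclei.

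**Figure D3:**
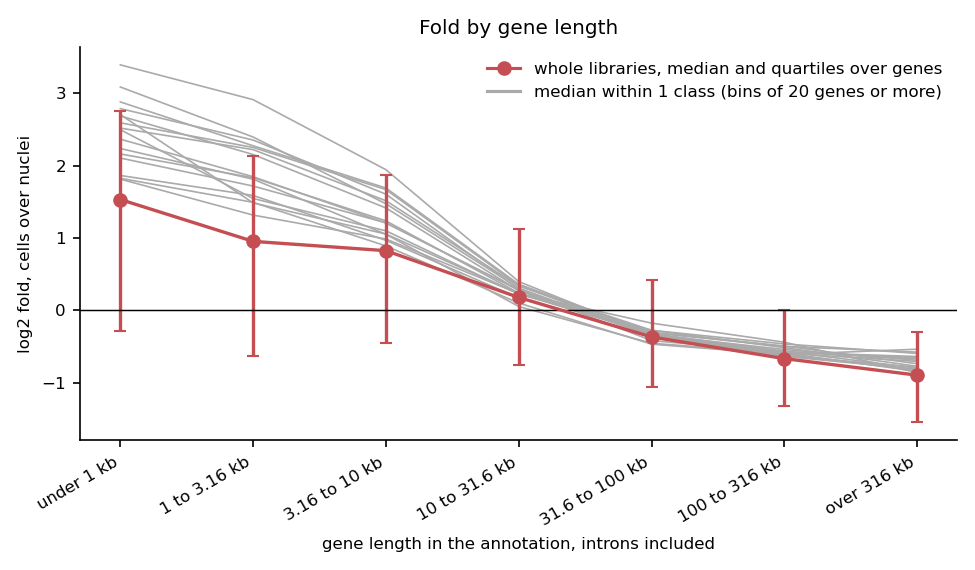
Median log2 fold, cells over nuclei (vertical axis, log2 scale), by bin of gene length (horizontal axis, introns included); points are medians over whole libraries with bars from the lower to the upper quartile of genes, and grey lines are the medians of the 16 classes in bins of 20 genes or more. The whole-library median falls from 1.53 under 1 kb to -0.90 in the longest bin.

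The 2 nucleus libraries resembled each other more than either resembled the cells. Over the 10604 genes with a mean of 10 CPM or more in the 3 libraries, the correlation of log2 CPM across genes was 0.936 between nucleus replicates and 0.620 and 0.562 between cells and nucleus replicates 1 and 2. Of these genes 109 (1.03%) differed at least 4-fold between the nucleus libraries, and 1705 (16.1%) differed at least 4-fold between cells and the mean of the nucleus libraries. Their cell types differed as well. General capillary cells took 27.0% and 11.2%, ciliated cells 1.18% and 6.84%, and club cells 2.03% and 10.3%. Nuclei of the 2 libraries fell into separate clusters for AT2, AT1, general capillary and alveolar fibroblast.

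Abundant transcripts of 1 cell type were counted in barcodes of other types, more so in nuclei for Scgb1a1 and Sftpc. After thinning to 1000 UMIs, Scgb1a1 was found in at least 99.9% of nuclei in all 8 classes examined, B cells and pericytes included. It took 15416 and 19191 CPM in club nuclei and from 11416 to 31251 CPM in the other classes. In cells it was found in 48.8% of pericytes and 58.8% of T/NK/ILC2, and in 81.1% of ciliated cells (73.1 to 87.7%). Sftpc was found in 87.0 to 99.3% of nuclei outside AT2, against 97.8% and 99.3% of AT2 nuclei. In cells it was found in 45.1 to 55.8% outside AT2 against 97.3% of AT2 cells (95.5 to 98.6%). Sftpc took 50380 CPM in AT2 cells and 4275 and 6278 CPM in AT2 nuclei. In the other classes of nuclei examined it took 1992 to 5941 CPM. Hbb-bs was found in 8.52% of B cells, and in 19.7% and 7.04% of B cell nuclei of replicates 1 and 2. By level it was higher in cells, at 500 CPM in B cells against 247 and 80.1 CPM in B cell nuclei. The same order of levels held in every class examined in both groups. Median depths were 2482 UMIs in T/NK/ILC2 cells and 3223 in AT2 cells, and 2756 and 4490 in the matching nuclei of replicate 1. Shares of barcodes with a UMI of these genes are therefore read as background outside the source. The calls for Cyp2f2, Scgb1a1, surfactant and haemoglobin genes in classes that do not make them carry this background. The epithelial genes Col4a3, Rtkn2 and Tmem212 were also lower in cells in at least 12 classes, and may carry it too.

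**Figure D4:**
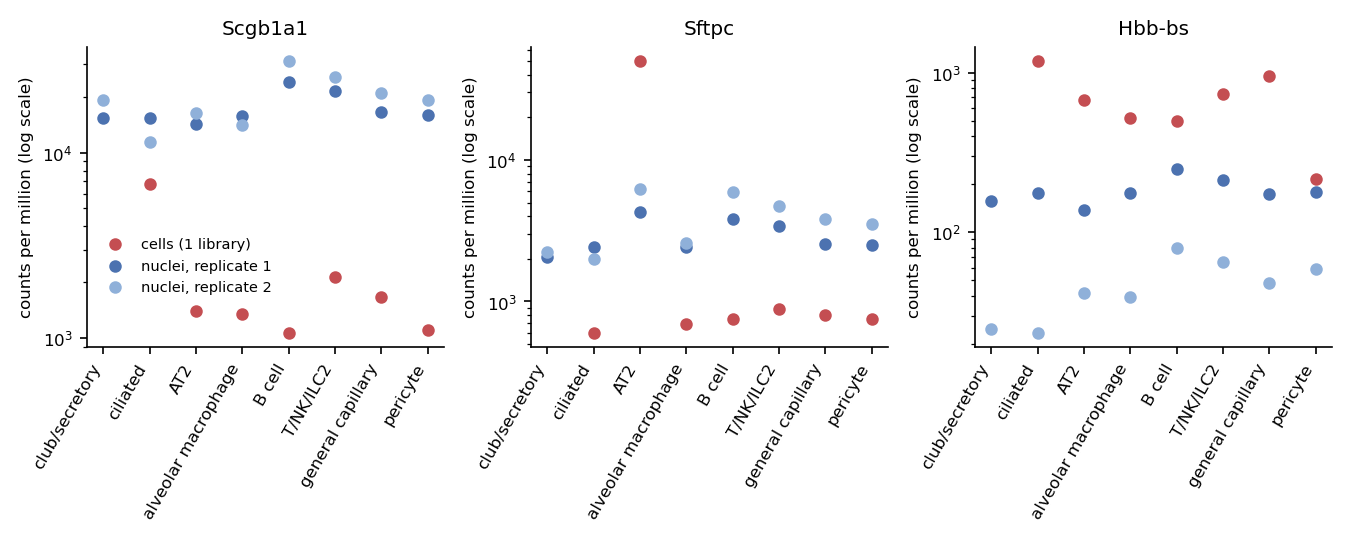
CPM (vertical axes, log scale) of Scgb1a1, Sftpc and Hbb-bs by cell class (horizontal axes) in the cell library and nucleus replicates 1 and 2; each point is 1 class of 1 library. Scgb1a1 is spread over every class of nuclei at 11416 to 31251 CPM, while Sftpc in cells peaks in AT2 at 50380 CPM.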

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

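The test of Ptprc was written before its result was known, and all other tests here were chosen after seeing the result. The bounds used to read the tests (0.25, 0.5 and 2) were own choices, and no biological explanation was tested beyond those named.

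Immediate early genes such as Fosb and Fos were higher in cells in every class. Over whole libraries short length does not account for this, since the list lay at percentile 100 of random lists matched on expression and length. The genes were not matched on length within classes. Free RNA of 1 source in the cell suspension, as the only source, would hold their ratios to Junb constant over classes. The ratios varied by a median SD of 0.611 log2 beyond counting error, which is close to the bound of 0.5. Free RNA beside expression in each class would also give varying ratios, so a part from free RNA is not excluded. A response to digestion of fresh tissue could raise these genes, but 0 animals are named with both kinds of library. It therefore cannot be told apart from animal, from freezing or from the difference between whole cells and nuclei. The nucleus libraries differ in Xist and Uty, yet Fosb stood at 0.435 and 0.516 CPM in them, and the list median stayed at 3.45 to 3.56 with either left out, which argues against sex as the cause.

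Club transcripts were higher in nuclei of classes that are not club cells. Their ratios to Scgb1a1 varied over classes by a median of only 0.0665 log2 beyond counting error in nucleus replicate 2. This value rests on Scgb3a2, Cyp2f2, Hp and Sec14l3, the markers with enough counts. Free RNA of 1 source in the nucleus suspensions would give such constant ratios. Doublets with club nuclei would give them too, so the ratios do not decide between these explanations. Doublets with club nuclei are unlikely as the cause, since Gabrp reached a median of 5.46% of its club level over classes outside the epithelium in nucleus replicate 2 (highest 14.6%), while the medians of Scgb1a1 were 102% and 93.0% in nucleus replicates 1 and 2.

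Immune barcodes were more frequent in the cell library. The ratio of shares was 4.10 within a common window of genes, but barcodes lost above the limits before deposit are in no window, so an effect of the limits cannot be told apart. Naming of clusters is unlikely as the cause, since thinned barcodes with Ptprc, the pan-leukocyte phosphatase, were 3.02 times as frequent in cells (44.8% against 12.9% and 16.8%). Ptprc was, however, also found in 24.6% of cell barcodes outside the immune compartment, against 3.77% and 7.68% of nuclei, so background adds to that ratio. A different yield of cell types could give the same difference, but with 0 animals named with both kinds of library it cannot be told apart.

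Aldoa, held by the nucleus table only, reached 54.6 CPM in nucleus replicate 2, a value not used in the comparisons. Eif2s3y, a gene of the Y chromosome held by the nucleus table only, reached 84.1 CPM in nucleus replicate 2. Fam71a, held by the cell table only, reached 17.4 CPM there. The median of matrix genes was higher in alveolar fibroblasts than in B cells by 2.05 log2, and this difference was not tested. The median of vascular genes was higher in pericytes than in B cells by 2.88 log2, and this difference was not tested.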

How the results depend on the processing

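Most alternatives were set before the data were examined; the tests within a common window of genes per barcode, with mixed clusters named, with lists matched on gene length, with doublets kept over whole libraries and with a nucleus library left out within classes and for gene length were chosen after seeing the result. Of the named genes in their own comparisons and the gene lists, none that had passed its test changed direction, and for those that moved the cause was not tested. The vascular and viral entry medians, which had not passed, changed sign, and the split in alveolar macrophages turned from 3173 higher and 2049 lower to 2224 and 2827 under the scaling without mitochondrial and ribosomal protein genes and Malat1. No paired analysis was possible because no animal is named with both kinds of library.

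With the 5% highest doublet scores removed, the cell library had 51.7% immune, 23.9% endothelial, 5.40% epithelial and 5.97% mixed barcodes. At 1000 genes or more the immune share was 49.9% in cells and 13.9% in nuclei, with 6.83% of cells mixed. In the common window the immune share was 50.4% in cells and 12.3% in nuclei, the endothelial share 23.8% in cells and the mesenchymal share 19.8% in nuclei. At Leiden resolution 0.5 cells had 47.7% immune, 15.2% mesenchymal and 1.42% mixed barcodes, and at Leiden resolution 2 they had 50.1% immune, 5.83% epithelial and 6.36% mixed. With more variable genes cells had 49.4% immune and 8.002% mixed, and with mixed clusters named 56.8% immune and 0% mixed. Under DESeq2 the within-class difference, cells against nuclei: median over classes of genes higher in cells, went from 1543 to 524. The within-class difference, cells against nuclei: median over classes of genes lower in cells, went from 816.5 to 219.5. With genes at 10 CPM or more the median of immediate early genes was 3.18, of vascular genes -0.40, of viral entry factors 1.33 and of apoptosis and p53 targets 0.89. With library sizes without mitochondrial and ribosomal protein genes and Malat1 it was -1.16 for long non-coding RNAs and 1.29 for apoptosis and p53 targets. Leaving out 1 nucleus library gave 3.45 to 3.56 for immediate early genes, -1.21 to -1.20 for long non-coding RNAs, -0.49 to -0.24 for matrix genes and 1.34 to 1.37 for apoptosis and p53 targets. Of 1512 alternatives for named genes 1471 counted as the same and 41 lost the call, 29 of them under DESeq2. The 216 without nucleus replicate 1 and the 216 without nucleus replicate 2 had no test. They were compared by direction alone, which all of them kept, so they could not lose a call. Results per class were less stable: 235 of 863 values moved for gene lists, 57 of 160 for gene counts (31 of 32 under DESeq2) and 78 of 506 for class shares.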

Other observations

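The calls named here come from the planned edgeR tests, and no tests were added after seeing the result. The nucleus libraries differed in sex-linked genes. Xist, which silences the second X chromosome of females, stood at 308 CPM in cells, 1041 CPM in nucleus replicate 1 and 8.80 CPM in nucleus replicate 2. The Y chromosome gene Uty stood at 1.11, 0.943 and 245 CPM, Ddx3y at 7.76, 1.41 and 83.5 CPM and Kdm5d at 1.11, 0.617 and 60.6 CPM. The sex of the animals is not given in the labels used here, and calls for Uty rest on nucleus replicate 2.

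Dgcr8, a partner of Drosha in the making of microRNA, and Ccdc141 were lower in cells in all 16 classes. In nuclei, 25 and 15 barcodes of replicates 1 and 2 stayed without a class.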
